A study of Mus musculus with 2 samples.

How the data were processed

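Hi-C, which ligates and sequences DNA ends that lie close together in fixed nuclei, was run on hair matrix keratinocytes of mice at postnatal day 4.5. Hair matrix keratinocytes are the dividing epithelial cells at the base of the follicle that give rise to the inner root sheath and the hair shaft. There were 2 libraries, 1 from wild-type mice (WT) and 1 from mice in which Tet2 and Tet3 were deleted with a Krt14-driven Cre recombinase (Tet2/3 DKO, here DKO). TET2 and TET3 are dioxygenases that oxidise 5-methylcytosine. Per the labels' protocols, sorted cells were fixed in 2% formaldehyde for 10 minutes, digested with the Arima enzymes, labelled with biotin, re-ligated, sheared to between 300 and 500 bp and sequenced as read pairs of 150 bp. Sequencing depth, read filters and the aligner are not given in the sources used here.

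The deposited values are a list of enriched pixels per library, a pixel being a pair of 5 kb bins on 1 chromosome. Per the file headers the lists were written by juicer_tools 1.22.01, and per the submitters' processing notes the tool was Juicer and the build GRCm38 (mm10). The layout is that of the HiCCUPS step of that tool before pixels are merged into loops. For each pixel the authors deposited the observed contact count, a raw count without normalisation. They also deposited, as a signal on the scale of those counts, the contacts expected from 4 surrounding neighbourhoods (bottom-left, donut, horizontal and vertical), and a score that numbers the class of expected counts. The deposited q-values, 1 false discovery rate (FDR) per neighbourhood, were all under 0.1 in both lists. Nothing is recorded for pixels that were not called, so absence from a list says only that no pixel was called there.

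Pixels of a chromosome were joined into loops by single linkage where both anchors lay within 20 kb, and a loop was placed at its pixel with the highest observed count. A loop was shared where any of its pixels had a pixel of the other library within 2 bins (10 kb) at both anchors. Enrichment is the observed count divided by the donut expected count. Relative depth was taken as the DKO/WT ratio of expected counts at pixels listed in both libraries, because the sum of a list of called pixels is not a sequencing depth. That sum was 113348 contacts in the WT list and 95103 in the DKO list.

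Genes came from a RefSeq table of GRCm38.p6, the build of the lists. The table gives gene starts and ends and no strand, so transcription start sites could not be placed, although the planned definition used them. A gene was instead counted at a loop where either annotated end of a protein-coding gene lay within 5 kb of an anchor bin of any pixel of the loop. Planned measurements of CTCF motif orientation and CpG content at anchors need a genome sequence and were not run. Coordinates are 1-based.

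With 1 library per genotype there was no test, no p-value and no replicate check. A difference between the lists compares these libraries and cannot be assigned to genotype. Intervals are exact 95% intervals, Poisson for counts, conditional binomial for ratios of counts and Clopper-Pearson for shares. They cover counting error only, take expected counts as fixed, and treat pixels and loops as independent, which neighbouring ones are not. The median of enrichment ratios has a bootstrap interval over pixels, as has the difference between long and short spans in the ratio of expected counts.

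There were 13 gene lists and 17 gene cluster loci, fixed with the group of each sample and the other settings listed next before the data were examined. The lists were type I and type II keratins of the inner root sheath and hair, epidermal keratins, hair follicle transcription factors, the WNT pathway, BMP, SHH, NOTCH and FGF signalling, terminal differentiation and desmosome genes, DNA methylation, loop architecture, proliferation, and markers of melanocytes, of dermal papilla and fibroblasts, and of immune, endothelial and nerve cells. A list's number of genes at loops of a single library was placed as a percentile among 10000 random lists of genes with similar loop numbers. A locus was placed among 10000 draws of as many consecutive loops. Genes named were up to 4 members per list, taking first those at loops of 1 library and then those with most loops. Also named were the 10 loops per library of highest enrichment that were not shared, had at least 2 pixels and lay at a gene, the 5 shared pixels with the highest and the 5 with the lowest DKO/WT enrichment among those with at least 30 counts in each library, Tet2, Tet3, Krt14, and every locus with a loop. Other genes named were chosen after their values were seen.

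Alternatives were an FDR under 0.01 in all neighbourhoods, WT counts thinned to DKO depth, a minimum of 20 observed counts, removal of 1-pixel loops whose FDRs sum to over 0.02, linkage at 10 or 50 kb, matching at the exact pixel or within 1 or 5 bins, other expected counts, autosomes alone, and gene ends inside the anchor bin or within 10 kb. A minimum donut expected count of 1 and anchors inside gene bodies were added after seeing the data. The thinning rule uses classes of expected counts, whose boundaries were set to match 100% of the deposited class numbers after a first version had been run. A thinned WT pixel was kept only where its count reached the lowest count in the DKO list for its class in each neighbourhood. The step therefore applies DKO cut-offs as well as the DKO depth.

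The steps were tested on simulated data. All 200 simulated loops and all 100 shared ones were recovered. With 17433 candidate pixels, no difference in enrichment and a relative depth of 0.97, the recovered depth was 0.97 and the median log2 enrichment ratio at shared pixels was 0.04. A true log2 ratio of −0.32 was recovered as −0.19, so requiring a call in both lists pulls this measure upwards. Both simulated lists were held to the lowest counts of the WT list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.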

Results

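Chromatin contacts were mapped by Hi-C in hair matrix keratinocytes of WT and Tet2/3 DKO mice, with 1 library per genotype. The series title names control of epithelial differentiation by these dioxygenases, and the comparison asks which chromatin loops are called with and without them. The WT list held 5811 enriched pixels (95% interval 5663 to 5962) and the DKO list 4872 (4736 to 5011). The median observed count was 18 contacts per pixel in both lists. Expected counts at shared pixels put the DKO library at 0.973 of the WT depth (quartiles over 1940 pixels 0.904 and 1.05). There were no replicates, so no value below has a replicate error.

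Of the genes the genotype concerns, Tet2 (chromosome 3, 133463677 to 133545136) had no loop at either end in either library. Tet3 (chromosome 6, 83362373 to 83457208) had 1 loop in the DKO list and none in the WT list. The highest pixel of that loop had 27 observed contacts at 5.54 times the expected count (3.65 to 8.06). That pixel lay over 5 kb from either end of Tet3, and only another pixel of the loop met the 5 kb rule. At an FDR under 0.01, or with gene ends inside the anchor bin, Tet3 was at no loop in either list. Krt14, the basal keratin whose promoter drives the Cre, had 1 shared loop, observed at 3.87 times expected in WT (2.55 to 5.63) and 3.55 times in DKO (2.34 to 5.16). Contacts do not measure transcripts or deletions, so these values do not check the genotype labels.

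Pixels formed 2902 loops in WT and 2641 in DKO, and 1453 loops of each list were shared. Shared loops made up 50.1% of WT loops (48.2 to 51.9) and 55.0% of DKO loops (53.1 to 56.9). Shared loops lay, for example, at an anchor between Krt28 and Krt10 on chromosome 11, at Krt78 and Krt8 on chromosome 15, and over 825 kb in WT and 840 kb in DKO from Shh, the hedgehog ligand of the follicle. The DKO/WT ratio was 0.838 for pixels (0.807 to 0.871) and 0.910 for loops (0.863 to 0.960). Loops without a counterpart were mostly single pixels, 83.6% of 1449 in WT (81.6 to 85.4) and 89.8% of 1188 in DKO (88.0 to 91.5), against 33.2% and 42.0% of shared loops. A match of any pixel makes a loop shared, so loops of more pixels have more chances, and part of this contrast follows from the rule. WT counts were also thinned to the DKO depth and held to the lowest counts of the DKO list. Over 100 draws WT then kept 4940 to 5024 pixels and 2493 to 2543 loops, so the order of the loop counts turned around. The effect of depth was not separated from that of the cut-offs. The DKO share of all loops in 1 such draw was 51.3% (49.9 to 52.6), against 47.6% as deposited. At the lowest of the depth estimates, 0.955, WT kept 4636 to 4743 pixels, and the order of the pixel counts turned around as well.

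Loops listed in DKO were shorter, with a median span of 100 kb against 115 kb in WT. Loops under 200 kb were about as many in both lists, 2041 in DKO and 2113 in WT, a ratio of 0.966 (0.908 to 1.03). Loops of 200 to 500 kb numbered 513 against 671, a ratio of 0.765 (0.680 to 0.859), and loops of 500 kb to 1 Mb 72 against 105, a ratio of 0.686 (0.501 to 0.934). The few longer loops did not follow, with 13 against 11 at 1 to 2 Mb (1.18, 0.489 to 2.91) and 2 in each list over 2 Mb. Among the loops without a counterpart, the WT list held long ones at Ctnnb1 (335 kb), which encodes β-catenin, and at Sox2 (835 kb). The DKO list held long ones at Dkk1 (305 kb), a secreted WNT inhibitor, and at Pds5b (695 kb), a cohesin regulator. The Sox2 and Pds5b loops were single pixels of 12 contacts each, on expected counts of 0.685 and 1.05. The Ctnnb1 and Dkk1 loops had 16 and 18 contacts. Among loops without a counterpart the ratio was 0.545 at 200 to 500 kb (0.454 to 0.653), and the median span was 115 kb in WT and 85 kb in DKO. Shared loops, which match by definition, had a median of 115 kb in both lists. The gap narrowed with stricter calling: at an FDR under 0.01 the medians were 115 kb in DKO and 120 kb in WT, and 26.0% of DKO loops against 27.1% of WT loops spanned over 200 kb.

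**Figure D1:**
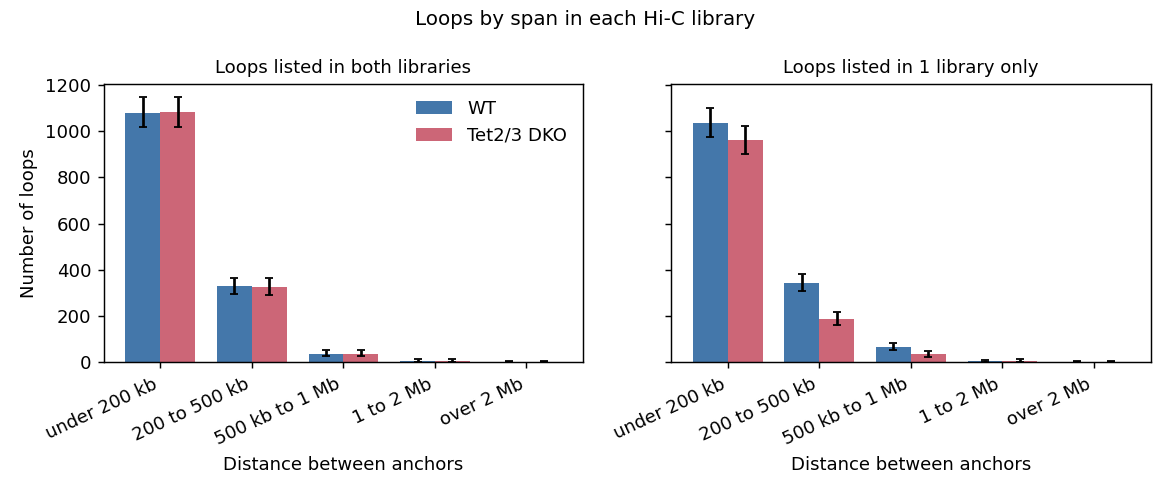
Loops by distance between anchors in the WT and DKO lists, with exact 95% intervals for counting error. Shared loops are at left and loops listed in 1 library at right. Shared loops number 1079 in WT and 1081 in DKO under 200 kb, and 328 and 326 at 200 to 500 kb. Loops of 1 library number 1034 in WT and 960 in DKO under 200 kb, and 343 and 187 at 200 to 500 kb.

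At the 1940 pixels listed in both libraries, median enrichment was 5.42 times expected in WT and 5.34 in DKO. The median log2 ratio DKO/WT was −0.02 (−0.05 to −0.01), with quartiles of −0.25 and 0.20, and its interval included 0 under 5 of 6 other settings. In 1 simulated pair of lists without a difference, both held to the WT cut-offs, this median was 0.04. The measured DKO list has its own cut-offs, so whether 0.04 is the value of no change for the measured lists is unknown. The pixel with the highest ratio joined both ends of Tmem267 on chromosome 13 (119485001 to 119490000, which also holds an end of 4833420G17Rik, and 119610001 to 119615000). It had 68 contacts in DKO and 35 in WT, expected counts under 1 in both, and a ratio of 3.08 (2.02 to 4.78), and a neighbouring pixel had a ratio of 2.25 (1.48 to 3.48). A pixel on chromosome 1 (132120001 to 132125000 and 132155001 to 132160000) without a gene end (1.61, 1.01 to 2.62) followed. Next came a pixel at ends of Clptm1, Apoe, Tomm40, Gm44805 and Apoc2 (1.53, 0.984 to 2.40). The last was at ends of Rfng, Cenpx, Lrrc45, Rac3, Gps1 and Dcxr (1.51, 0.936 to 2.46). The lowest ratios outside chromosome 17 were at a pixel on chromosome 11 (103760001 to 103765000 and 103910001 to 103915000), 0.584 (0.357 to 0.943), whose loop reached Wnt3 through other pixels. Gadd45b, a stress gene linked to DNA demethylation, followed with 0.593 (0.369 to 0.937), and a pixel on chromosome 2 starting at 170450001 with 0.631 (0.375 to 1.05). The 2 lowest ratios, 0.412 and 0.508, belonged to a contact over 3610 and 3615 kb on chromosome 17 with expected counts under 0.1, next to an 18S ribosomal RNA pseudogene. Single-pixel intervals left out a ratio of 1 at 31 of 1940 pixels (1.6%), 11 higher and 20 lower in DKO, without adjustment for their number. Exact 95% intervals hold a true ratio of 1 at 95% of pixels or more, so this share shows no excess over counting error. The pixels named here are the ends of a ranking of 146, and their intervals do not allow for that choice. The highest pixel of the Gadd45b loop stood at 8.13 times expected in WT and 5.92 in DKO, a smaller gap than at the ranked pixel.

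**Figure D2:**
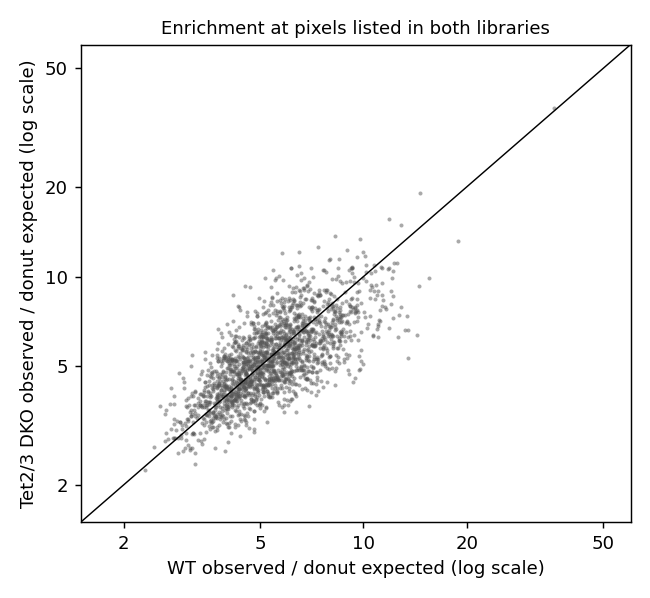
Observed over donut expected contacts in WT (horizontal, log scale) and DKO (vertical, log scale) at pixels listed in both libraries with a donut expected count of at least 1. Points lie around the line of equal values, and the median log2 ratio over all 1940 shared pixels is −0.02.

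An annotated gene end lay at 70.5% of WT loops (68.8 to 72.1) and 71.5% of DKO loops (69.7 to 73.2). Of 21900 protein-coding genes, 2067 were at loops in both libraries, 1501 in WT alone and 1422 in DKO alone. Of these last groups, 198 and 229 genes lay at a loop that was itself shared, so the gene count and the loop count differ in what they call shared.

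Of the inner root sheath and hair keratins, 2 of 11 type I members and 2 of 9 type II members found were at loops. Over all protein-coding genes, 4990 of 21900 were at a loop in at least 1 library. Krt28 was at loops in both libraries, and Krt25 at 1 DKO loop (3.81 times expected, 2.44 to 5.67), among the 11 type I members. Among the type II members Krt72 was at loops in both libraries and Krt84 at 1 DKO loop (4.66, 2.55 to 7.82), with 9 of 11 members found in the gene table. Of 12 epidermal and outer root sheath keratins, Krt10 and Krt14 were at shared loops. Of the 33 hair follicle transcription factors 11 were at loops, 9 of them in both libraries, including Cux1 and Msx1. Matched random lists had on average 1.39 members in WT alone and 1.30 in DKO alone, against 1 and 1 here, and without weak 1-pixel loops the list had 5 in both, 4 in WT alone and 1 in DKO alone. Tcf7l1, a repressor of WNT targets, had a WT loop (3.85, 2.47 to 5.74), and Vdr, the vitamin D receptor, a DKO loop (4.89, 2.85 to 7.83).

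In the WNT pathway 13 of 32 members were at loops, 7 in both libraries, 3 in WT alone and 3 in DKO alone. Matched random lists averaged 3.39 members in WT alone and 3.16 in DKO alone. Axin2, a WNT target, Dkk1 and the receptor Fzd2 were at DKO loops, with 6.02 (3.2 to 10.3), 8.12 (4.81 to 12.8) and 2.91 (1.80 to 4.45) times the expected contacts. The Axin2 loop was itself shared, and the WT pixels of it did not reach the gene. Ctnnb1 was at a WT loop with 6.20 (3.55 to 10.1). Of the 32 BMP, SHH, NOTCH and FGF members 17 were at loops, 7 in both, 6 in WT alone and 4 in DKO alone. For this list matched random lists averaged 4.98 in WT alone and 4.71 in DKO alone. Bmp2 was at 2 WT loops, and Edar and Edaradd, the ectodysplasin receptor and its adaptor, at 1 each (5.07, 2.96 to 8.12 and 4.29, 2.65 to 6.55). Bmpr1a was at a DKO loop (3.62, 2.32 to 5.38).

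Of 31 terminal differentiation and desmosome genes 10 were at loops, 3 in both, 2 in WT alone and 5 in DKO alone. Matched random lists averaged 3.72 in WT alone and 3.54 in DKO alone. The desmosomal genes Dsg3 (4.09, 2.34 to 6.65), Dsp (4.16, 2.57 to 6.35) and Perp (6.64, 4.30 to 9.80) were at DKO loops, and Jup, plakoglobin, at a WT loop (4.21, 2.80 to 6.09). The Perp loop was itself shared. At an FDR under 0.01 this list turned around, with 4 genes in WT alone and 0 in DKO alone. Of 18 DNA methylation genes 6 were at loops, Gadd45b among the 3 in both. Dnmt3l and Uhrf1 were at loops in WT alone and Tet3 in DKO alone. Matched random lists averaged 1.74 members in WT alone and 1.63 in DKO alone. With gene ends within 10 kb the order was 1 in WT alone and 2 in DKO alone. At an FDR under 0.01 only the 3 genes in both were left. The Dnmt3l loop was one of the shared loops, so that only the reach of its pixels to this gene differed. Of the 16 loop architecture genes found, 5 were at loops, Mau2, a cohesin loader, in WT alone and 4 in DKO alone, among them Ctcf (3.44, 2.07 to 5.37), Zfp143 and Pds5b. This DKO count had the highest percentile of the 12 lists with loops, 96.1 among random lists, unadjusted for their number, and 1 of the 4 genes remained at an FDR under 0.01. Without weak 1-pixel loops the list had 1 gene in WT alone and 1 in DKO alone. Of 23 proliferation genes 13 were at loops, 6 in both, 3 in WT alone and 4 in DKO alone. Matched random lists averaged 3.86 in WT alone and 3.68 in DKO alone. Ccnb1 and Cdkn1a were among those in WT alone. Aurkb, at a loop that was itself shared, and Ccna2 were among those in DKO alone.

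Markers of other cell types were also placed. None of 10 melanocyte markers was at a loop in either library, and 3 were with gene ends within 10 kb. Of 17 dermal papilla and fibroblast markers 6 were at loops, 4 in WT alone (Alpl, Col1a2, Sox18 and Sox2), Pdgfra in DKO alone and 1 in both. Of 17 immune, endothelial and nerve markers Cd4, Cdh5 and Hba-a1 were at WT loops and Pecam1 at a shared loop. Hba-a1, an alpha-globin gene, was fixed in this list but marks none of these cell types. The WT counts of both lists stood at percentiles 87.9 and 91.7 among random lists, at these small member numbers. The immune, endothelial and nerve list turned around to 0 in WT alone and 1 in DKO alone with gene ends inside the anchor bin, and likewise with anchors inside gene bodies.

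**Figure D3:**
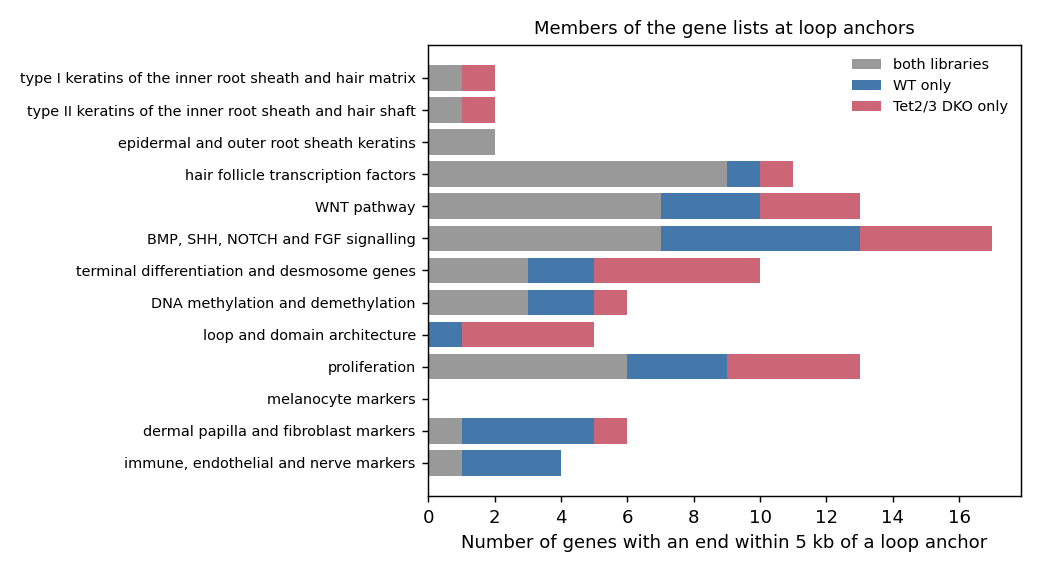
Members of each fixed gene list at loops in both libraries, in WT alone and in DKO alone. As deposited, 9 of 11 hair follicle transcription factors are at loops in both libraries and 4 of 5 loop architecture genes in DKO alone; without weak 1-pixel loops these become 5 of 10 and 1 of 2.

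Among loops of at least 2 pixels at a gene, the WT loops of highest enrichment without a DKO counterpart lay at Ndufaf4, Crygs and Ice1. The loop at Ndufaf4, a complex I assembly factor on chromosome 4 (24720001 to 24725000 and 24895001 to 24900000), had 17 contacts, 13.1 times expected (7.65 to 21.0). Those at the lens crystallin gene Crygs and at Ice1 stood at 12.5 (7.90 to 18.7) and 12.3 (6.72 to 20.6). Lrrc66, Spon1, Capn13, Cd40, Nav2, Mmp17 and Caln1 followed, from 11.8 down to 9.15. The DKO loops of highest enrichment without a WT counterpart lay at Pstpip2 (82.1), the imprinted gene Mest (29.4) and the olfactory receptor gene Olfr262 (15.1). Each had an expected count under 1 and 12 or 13 contacts. At Pstpip2 and Mest the donut expected counts were 0.146 and 0.408 and the bottom-left ones 0, so their ratios rest on nearly empty neighbourhoods. Riok2 (9.50, 5.95 to 14.4), Mplkip, Hoxa13, Rrp15, BC035044, Wdr75 and Igfbp3 (8.15, 4.46 to 13.7) followed. They were drawn from 180 WT and 94 DKO loops of at least 2 pixels at a gene. With a minimum expected count of 1, chosen after seeing the data, Pstpip2, Mest and Olfr262 gave way to Capn13, Mc5r and Hrh4.

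Among gene clusters, the Hoxa locus on chromosome 6 (52155367 to 52260880) held 4 DKO loops and no WT loop. They ran from Hoxa13 to bins starting at 52915001 (9.03 times expected, 4.81 to 15.4) and from Hoxa13 and Hoxa11 to 52835001 (7.83, 4.17 to 13.4). Another joined Hoxa10, Hoxa11 and Evx1 (4.25, 2.60 to 6.57), and the last ran over 1045 kb from Hoxa7, Hoxa9 and Hoxa10 to 51170001 (6.48, 3.63 to 10.7). Their observed counts were 13 to 20. The share of DKO loops at Hoxa stood at percentile 99.3 among runs of consecutive loops, unadjusted over the 13 loci with loops. No Hoxa loop was left in either list at an FDR under 0.01, and 2 were left when weak 1-pixel loops were removed.

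The Hoxb locus had 6 WT and 3 DKO loops, and its loop from Hoxb6, Hoxb5 and Hoxb3 over 250 kb was shared (4.39, 2.84 to 6.48 in WT and 4.51, 2.94 to 6.60 in DKO). At an FDR under 0.01 the order of Hoxb turned around to 1 WT and 3 DKO loops, that of Hoxd to 0 and 1, and that of the protocadherins to 1 and 0. Hoxc and Hoxd each had 2 WT loops and 1 DKO loop, 1 shared in each cluster. The type I keratin locus on chromosome 11 held 5 WT and 7 DKO loops, of which 3 were shared, and the type II keratin locus on chromosome 15 held 4 in each with 3 shared. Its strongest had its highest pixel at a bin inside Krt78 (101985001 to 101990000 in both libraries), with other pixels within 5 kb of gene ends of Krt78, Krt8 and Eif4b, and stood at 11.3 times expected in both (8.21 to 15.2 in WT, 8.54 to 14.7 in DKO). The epidermal differentiation complex on chromosome 3 held 6 WT and 7 DKO loops with 4 shared, including loops at S100a6 and S100a10. Protocadherins had 1 and 2 loops and peptidylarginine deiminases 2 and 1, with 1 shared in each locus and the shared deiminase loop at Padi3 and Padi2. The desmosomal cadherin and Serpinb loci each had 1 DKO loop and no WT loop, while the Irx locus of chromosome 13 and the Dlx3 and Dlx4 locus each had 1 shared loop. No loop was listed at the chromosome 16 and chromosome 7 keratin-associated protein loci, the Irx locus of chromosome 8, or Dlx1 and Dlx2.

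**Figure D4:**
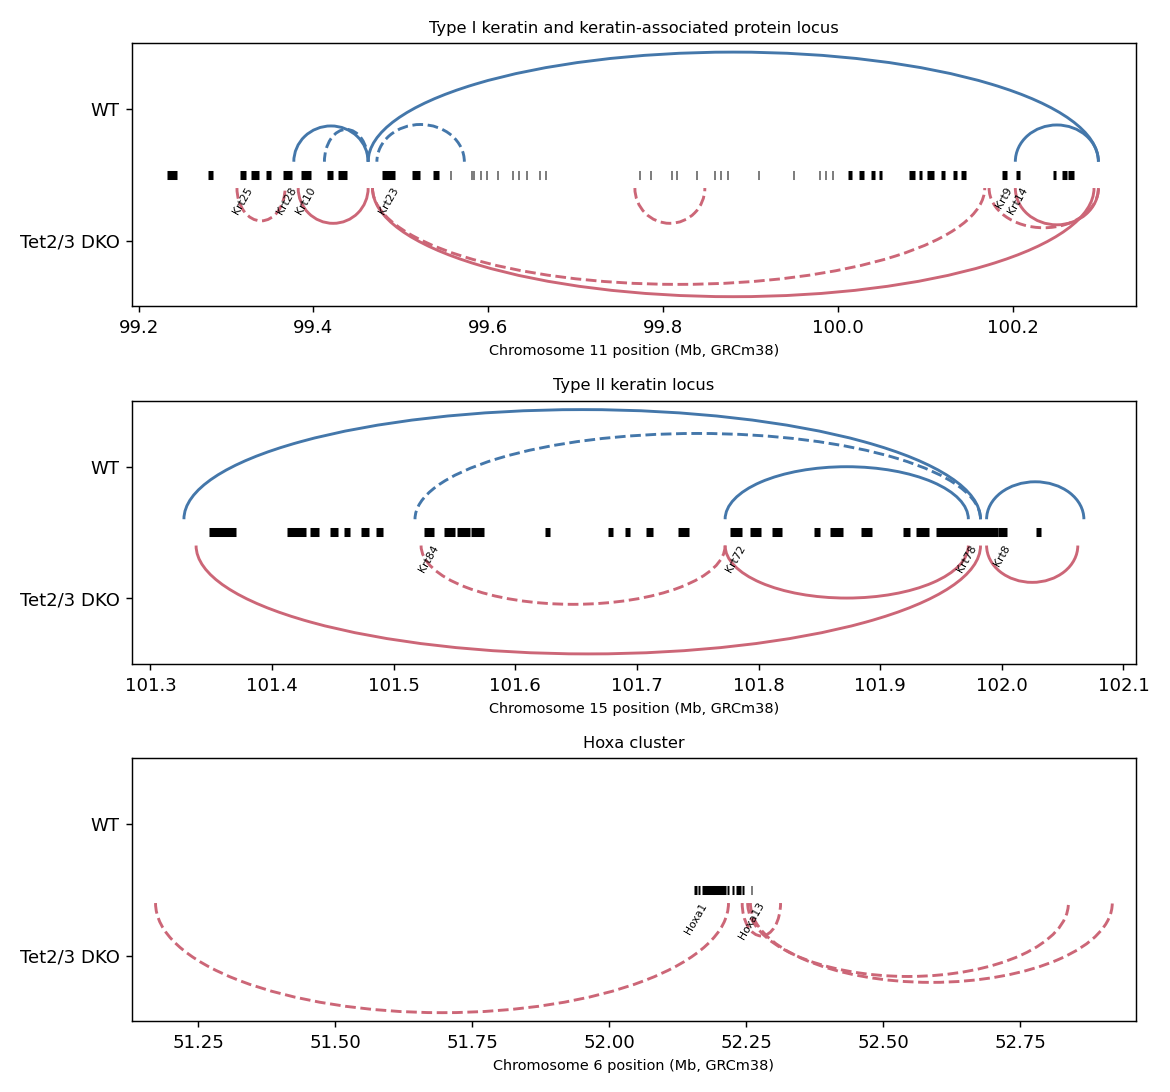
Loops at gene cluster loci, WT arcs above and DKO arcs below the genes, solid where shared and dashed where listed in 1 library, along GRCm38 coordinates. The Hoxa map holds 4 DKO arcs and no WT arc, and 3 arcs of each library are shared at each keratin locus; arc height grows with span and has no scale.

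No chromosome departed from the rest. DKO loops made up 43.2% (27.1 to 60.5, chromosome X with 21 WT and 16 DKO loops) to 51.2% (45.3 to 57.0, chromosome 6) of the loops of a chromosome, and every interval included the genome-wide 47.6%. Chromosome Y had 1 loop in each list.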

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

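No paired analysis was possible because each genotype has 1 library and no result comes from a test; leaving out a replicate and other splits of the samples were impossible for the same reason. Of 125 values recomputed under the alternatives, 70 stayed within their interval, or for counts within 1.5 times, 54 moved beyond it and 1 turned around. The 70 include values of the DKO list under thinning, which alters WT alone. Apart from the share of shared loops, those could not change. That 1 is the DKO share of loops crossing 50%; counting this as turned around was decided after its value was seen, and its interval (49.9 to 52.6) includes 50%. The cause of a move was not tested unless the alternative itself removes pixels or changes the match. The CTCF motif and CpG alternatives were not run for lack of a genome sequence, and the tolerance of the match does not enter the gene lists. Depth limits every absence: a loop missing from a list was not called there, and the sequencing depth is unknown.

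Apart from these values, the order of WT and DKO turned around in 3 gene lists and 3 loci, each named beside its counts above.

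At an FDR under 0.01, which removes pixels, WT kept 2500 pixels and 1419 loops and DKO 2010 and 1210, and the DKO share of both lists became 44.6% for pixels and 46.0% for loops. Shared loops were then 52.0% of WT and 61.0% of DKO loops, the DKO median span 115 kb with 26.0% over 200 kb, genes at loops 1767 in WT and 1598 in DKO, list members 43 and 36, and loops in loci 19 and 21. Thinning WT to the DKO depth and holding it to the DKO cut-offs can only remove WT pixels. The DKO share was then 49.6% of pixels and 51.3% of loops, and shared loops were 54.8% of WT and 52.0% of DKO loops. With at least 20 observed counts, WT kept 2325 pixels and 1202 loops and DKO 1902 and 1029, with a DKO share of loops of 46.1% and with 53.9% and 62.9% shared. This filter favours short spans, and the medians were 85 kb in WT and 75 kb in DKO with 15.2% and 13.2% over 200 kb. Without weak 1-pixel loops there were 1710 WT and 1424 DKO loops (DKO share 45.4%), 56.4% and 67.8% shared, medians of 125 and 115 kb, 25.8% of DKO loops over 200 kb, and 2320 and 2135 genes at loops.

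Linkage at 50 kb gave 57.1% of DKO loops shared. Shared WT and DKO loops were 36.5% and 40.1% at the exact pixel, 47.4% and 52.1% within 1 bin, and 52.2% and 57.5% within 5 bins. Gene ends inside the anchor bin gave 2067 genes in WT and 1969 in DKO, and 39 and 38 list members. The bottom-left expected count gave a median log2 ratio of −0.0058 at shared pixels and a relative depth of 0.955, and the vertical one a depth of 0.966. The median log2 ratio at shared pixels was below 0 under each of 6 alternatives, with an interval that included 0 under 5 of them. In 1 simulated pair of lists each, no difference came out as 0.04 and a true −0.32 as −0.19. In such lists this measure understates a decrease, and 0 is not its value for no change. The simulation assumed the spread of enrichments, a depth ratio of 0.97 at every pixel, and the WT cut-offs for both lists. How far its values hold for the measured lists is unknown.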

Other observations

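The predictions of the 5 tests below were written before their results were seen; the loops of the next paragraph were picked after their values were seen. Among shared loops of at least 2 WT pixels with an expected count of at least 1 in both libraries, ranked by the lower of both enrichments, the first lay at Psph, the last enzyme of serine synthesis, on chromosome 5 (129785001 to 129790000 and 129845001 to 129850000), with 35.9 times the expected contacts in WT (26.4 to 47.8) and 36.7 in DKO (26.4 to 49.6). A shared loop at Nkain1 with expected counts under 1 stood higher, at 44.8 (29.0 to 66.1) and 49.8 (33.6 to 71.1). Loops at Rtl9 on chromosome X (11.9 and 13.7), Cdkn1c, an imprinted inhibitor of the cell cycle (11.8 and 10.6), and Irx1 (12.2 and 10.5) were also near equal in both libraries. So was a loop from Cebpb over 215 kb, with 59 contacts in WT and 58 in DKO. Wnt7b, a WNT ligand of the follicle, had the most loops of any gene when both lists were summed, 5 in WT and 3 in DKO. In the DKO list alone Chit1, Nkain1 and Pard6g had more, 4 each. The strongest Wnt7b loop stood at 11.2 times expected in WT (8.02 to 15.2) and 7.10 in DKO (4.68 to 10.3).

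The DKO list held fewer pixels and shorter loops. Thinning argues against a loss of long WT pixels at lower depth as the cause of the shorter loops. The median WT span stayed at 115 kb in all 100 draws, on a grid of 5 kb, and the share over 200 kb stayed between 26.0% and 27.2%. Loops listed in DKO alone had a median span of 85 kb. Thinning cannot add such loops to the WT list, so any part of depth in them was not tested. At shared pixels, the median DKO/WT ratio of expected counts over 200 kb minus that under 100 kb was 0.0073 (bootstrap interval −0.0107 to 0.0205). This argues against a steeper fall of contacts with distance at those 392 and 864 pixels. Long pixels listed in WT alone have no DKO value, so the test cannot exclude it there. Lower depth as the cause of the lower pixel count stays open, because thinning to the lowest depth estimate left 4636 to 4743 WT pixels, in every draw under the DKO count of 4872 and its upper limit of 5011, while the donut estimate left 4940 to 5024. Thinning cannot add pixels, and it also applies the DKO cut-offs, so these counts do not show the effect of depth alone. In simulated data without a difference, the thinned list held 97.4% of the count of the other list. With a true log2 ratio of −0.32 it held 176.5%. The genotype, the mouse and the library may each account for the shorter loops, and a stricter FDR moves the DKO median to 115 kb against 120 kb.

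Many pixels were listed in 1 library, and counting noise at the calling threshold is a candidate explanation. Among the 1455 strongest WT pixels, with counts at least 1.27 times the calling threshold of their class, 87.3% had a DKO pixel within 2 bins, 5.97 percentage points below the 93.3% that Poisson counts of the same mean would reach. That Poisson share asks for the exact pixel, where like for like 61.6% of the strongest pixels were listed, and 34.7% against 73.7% and 17.9% against 53.0% in the weaker groups. It also takes each observed count, selected for being high, as the true mean and is therefore an upper bound, so noise and a difference between the libraries cannot be told apart here. The Hoxa loops are among these pixels, and whether they belong to the genotype was not tested.

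The pixel with the highest count in both lists joined bins 3615 kb apart on chromosome 17 (344 contacts in WT and 292 in DKO). A neighbouring pixel of the same contact had 253 and 161, and no pixel outside it had more than 68 in either list. Of the anchors of the highest pixel, 1 holds an annotated rRNA gene, Rn18s-rs5, an 18S rRNA pseudogene at 39846354 to 39848202. Reads shared between copies of ribosomal DNA may therefore account for this contact and for its low DKO/WT ratio, and it is not described as a loop of the follicle.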
